A study of Mus musculus with 4 samples.

How the data were processed

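The libraries were made by droplet sequencing with the 10x Genomics 3' chemistry from T cells pooled over 5 tissue compartments, with 1 expression and 1 hashtag library for each of 2 replicates. Per the file headers and the labels, the authors made each count matrix with Cell Ranger 3.1.0 against mm10. The deposited values are counts, that is raw UMI counts per gene and barcode, with no normalization and over all 6794880 barcodes of the chemistry, so cells were selected here. The feature lists of all 4 libraries were checked and are identical: each holds 31053 genes and 0 hashtag features. Without a hashtag count no cell has a tissue, and tissue was never inferred from expression. The 10 planned comparisons between tissues, the tests of cell shares by tissue and the hashtag alternatives were therefore not analysed here.

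Barcodes with at least 1000 UMIs and 500 genes and at most 10% mitochondrial UMIs were kept. In replicate 1, 19662 barcodes had 1000 UMIs, 19624 of these passed the gene minimum and 604 of these were removed by the mitochondrial limit. In replicate 2 the numbers were 17715, 17662 and 1764. Kept cells held 80.0% and 73.4% of all UMIs. Counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes, 30 principal components, 15 neighbours and Leiden resolution 1 gave 20 clusters with scanpy 1.11.5 and igraph 0.11.9 under Python 3.11.15 (numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0). Resolutions 0.6 and 1.5 gave 14 and 26 clusters. The 10 leading genes of a cluster were those with the largest log2 fold over all other cells, with a pseudocount of 10 CPM, among genes with a UMI in at least 10% of its cells. A cluster was named where at least 3 of these were markers of 1 of 17 fixed sets, and clusters named as another cell type were left out of the T cell sums. Scrublet's automatic threshold called 0 doublets in both libraries and so did not serve, and an alternative left out the 8% of cells with the highest score in each library.

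For shares and splits, each cell was thinned at random (seed 20) to 1500 UMIs, the largest multiple of 500 that at least 80% of cells reached in both libraries. Shares carry exact binomial (Clopper-Pearson) 95% intervals, which cover counting error only. Cells with at least 1 UMI of a gene after thinning were compared with cells without, on 4 sums of counts (2 libraries by 2 classes), with the gene itself left out. The test was edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) with TMM normalization, filterByExpr and the library as a block, since both classes came from the same library, and Benjamini-Hochberg adjusted p under 0.05 as threshold. Each fit had 1 residual degree of freedom. Of 29 gene lists, 28 had at least 3 measured members and were tested with camera, which compares a list with all other genes, at a preset correlation of 0.01 and again with an estimated one (limma 3.58.1). With an estimated correlation, camera rested on that 1 residual degree of freedom, so hardly any list could pass. A failure there therefore decides nothing about a list, and the preset correlation is an assumption. The p-values of camera were adjusted over the lists of a split. fry tested whether the members of a list move, on balance, in 1 direction. CPM values beside the splits are means of the 2 libraries. Gene positions are from GENCODE's annotation of mm10, matched by gene identifier for 207 of 207 genes looked up.

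The cell filters, cluster settings, marker sets, gene lists, thinning rule, Tcf7 split and rule for named genes were planned before the data were examined. In that plan, the Tcf7 split and the thinning rule worked on samples by tissue and replicate, and the cell filters also used hashtags. Without hashtag counts, the split and the thinning rule were applied per library, and the hashtag filters were dropped. The form of the split used here was thus set after the hashtag libraries had been read. The named genes were a panel of 17 genes, up to 4 genes past the threshold with the largest change from each list, and the 10 largest rises and falls among genes past the threshold with at least 50 CPM in the higher class and both libraries in the same order. The 10 largest falls without clusters 15, 19 and 20 were added later. The text prints part of this set. Genes given for the clusters and libraries outside this rule, such as the leading genes, were chosen after their values were seen. The Itgae and Pdcd1 splits were also added later, from the panel. Alternatives were RLE size factors, no low-count filter, the Wald test of DESeq2 1.42.0, no thinning, no replicate block and all cell types kept. Alternatives added after seeing the data were thinning to 1000 UMIs, a second random thinning, leaving out high doublet scores, and leaving out clusters led by S100a8 or Mcpt8, of mostly 1 library (over 85% of cells), of proliferating-like and of progenitor-like cells. The test was run on simulated counts with known changes. They were drawn gene by gene around 1 profile pooled over the sums, with the fitted trend of dispersion. The simulation had no difference in profile between libraries and no correlation between genes, so its false calls do not measure error in the real sums. For the Tcf7 split the test recovered 24.2% of genes with a log2 change of 0.5 and 60.2% of those with 1, with 3 false calls of 86. For the Itgae split it recovered 59.8% and 87.9% (4 false of 149 calls), and for the Pdcd1 split 44.4% and 74.5% (8 false of 125 calls).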

Results

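The series profiled CD4 T cells of mice with graft-versus-host disease (GVHD), in which transplanted donor T cells attack the tissues of the recipient. The sorted cells carry TS1, a transgenic T cell receptor, on a BALB/c background without RAG2, so that the transplanted T cells share a single receptor. Cells were taken 4 weeks after transplantation from spleen, colon, skin and small intestine, the last as intraepithelial and lamina propria cells, and were pooled for droplet sequencing with the 10x Genomics 3' chemistry. The 4 libraries are a gene expression library and a hashtag library for each of 2 replicates. Nothing in the labels says whether the replicates came from separate animals, so every p-value and SD given here rests on 2 pooled libraries only. An SD is the spread between them. The SE of a fold change comes from a fit that shares information across genes, so it can be smaller than the gap between libraries. The p-values of camera compare genes with genes and do not measure that spread. The expression library of replicate 1 held 89427990 UMIs, of which 71504017 lay in 19020 kept cells (median 2688 UMIs and 1203 genes per cell). The library of replicate 2 held 108082997 UMIs, with 79345397 in 15898 kept cells (median 3699 UMIs and 1485 genes).

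The tissue labels pose the question of how T cells of the target tissues differ from each other and from those of the spleen. The hashtag libraries as read here held 0 hashtag features and only gene UMIs, so no cell could be assigned to a tissue and the comparisons between tissues were not analysed here. Each library is therefore described as a pool of 5 tissues in unknown proportions. The comparison that the pool allows is between cells with and without UMIs of a chosen gene within the same library, first for Tcf7, the transcription factor of progenitor and stem-like T cells. Splits by Itgae and Pdcd1 were added after the hashtag libraries had been read. In every split the detected and undetected cells may come from the tissues in different proportions. The block in the fit is the library only, so a difference between classes cannot be told apart from one in tissue of origin.

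The pooled T cells had an abundant cytotoxic and chemokine profile. Ccl5, a chemokine of effector T cells, reached 30534 ± 2269.9 CPM (UMIs scaled to the same library total; mean ± SD, n = 2 libraries), and Gzma and Gzmb, which encode granzymes, reached 18016 ± 564 and 5834 ± 300.3 CPM. Ifng, the cytokine of type 1 helper cells, was at 834 ± 108 CPM, and Ccl4 at 3934 ± 508 CPM. Cytokines of other helper programmes were lower, with Csf2 at 146 ± 11.4, Il13 at 67.7 ± 7.04, Il10 at 47.7 ± 10.6, Il22 at 7.67 ± 2.00, Il4 at 1.61 ± 0.221 and Il17a at 1.24 ± 0.587 CPM. Of the lineage transcription factors, Gata3 was at 72.4 ± 5.24, Eomes at 50.9 ± 3.86, Tbx21 at 39.4 ± 0.152 and Bcl6 at 6.25 ± 0.215 CPM. Foxp3, the factor of regulatory T cells, was at 0.303 ± 0.0608 CPM, with a UMI in 11 of 15042 cells of replicate 1 and 6 of 14719 cells of replicate 2 after every cell was thinned to 1500 UMIs. Cd8a was at 524 ± 33.7 CPM, above Cd4 at 193 ± 9.34 CPM, while Cd8b1, which encodes the second chain of the CD8 heterodimer, was at 48.8 ± 2.73 CPM. Per the labels the sort was for TS1 CD4 cells, and UMIs do not measure surface protein.

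Clustering gave 20 clusters. The progenitor-like cluster 8, led by Tcf7, Slamf6, S1pr1 and Klf2, held 4.39% ± 0.268 of the cells (SD, n = 2 libraries), and cells so named were 13.2% at resolution 0.6 and 6.30% at 1.5. The proliferating-like clusters 9 and 10 held 8.02% ± 0.484, and the interferon-response-like cluster 12, led by Ifit1 and Ifit3, held 1.48% ± 0.697, a name that no cluster reached at resolution 0.6. The other T cell clusters carried too few of the markers fixed in advance to be named. Among them, cluster 2 was led by Cd8a, Cela1, Cd244, Itgae and Gzma and held 13.8% ± 2.68. Cluster 3, led by Xcl1, Nr4a2, Ctla4 and Ccl4, held 11.5% ± 6.72. Cluster 4, led by Il10, Ccl4, Rgs16 and Eomes, held 11% ± 4.92. Cluster 5, led by Il13, Csf2, Ccl1 and Il1r2, held 9.54% ± 0.283. Cluster 7 was led by the heat shock genes Hspa1a and Hspa1b and held 7.23% ± 0.294. Cluster 1, of median 1478.5 UMIs per cell and with Abhd2, Actb and Upf1 leading, held 30.1% of the cells of replicate 1 and 3.93% of those of replicate 2. Clusters 16, 17 and 18 had markers of myeloid, erythroid and epithelial cells and were left out of the T cell sums with their 453 cells. Clusters 15, 19 and 20, with 315 cells, were led by the neutrophil genes Ngp, S100a8 and Camp or by the basophil genes Prss34 and Mcpt8. In replicate 1, cells of cluster 19 also had T cell transcripts, with Cd3e in 89.4% and Gzma in 100% of 47 cells at 1500 UMIs. Free RNA, taken from barcodes under 100 UMIs, holds T cell transcripts too. Over both libraries, Ccl5 was at 29864 CPM in cluster 19 and 28441 CPM in free RNA. Whether the transcripts were the cells' own was not tested. The rule fixed in advance did not remove clusters 15, 19 and 20. The number of genes called and the change of S100a8 are therefore also given without them. The list results are given with them in.

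**Figure D1:**
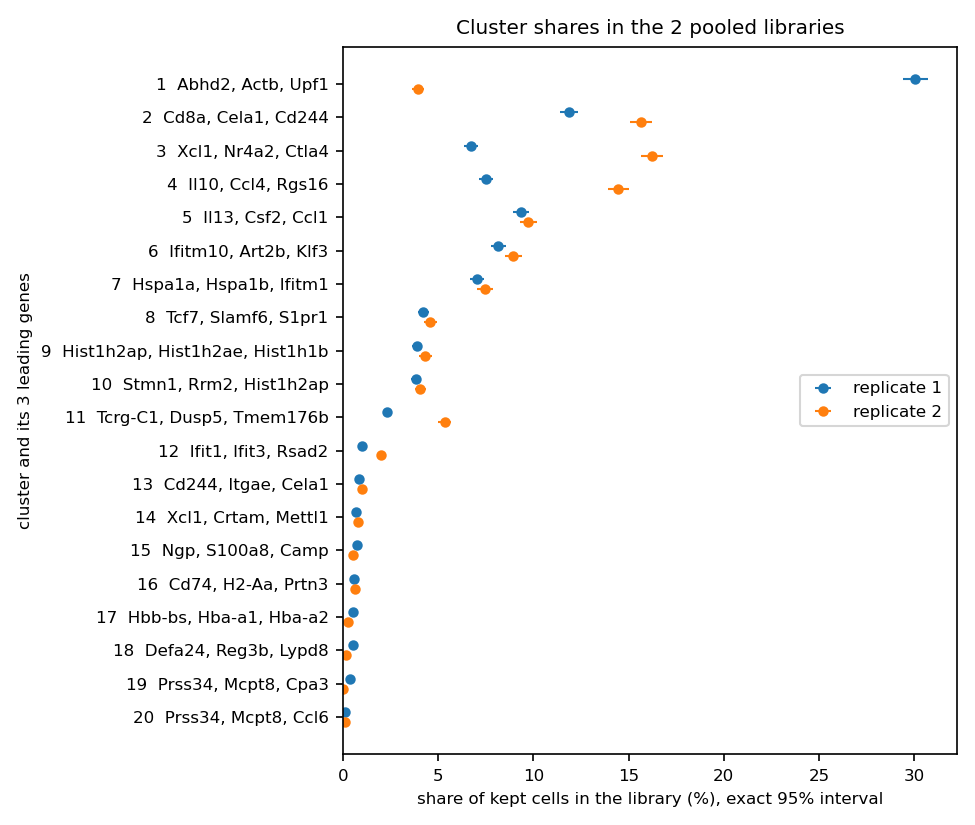
Share of kept cells (x axis, %) in each of the 20 clusters (y axis, with the 3 leading genes) for replicate 1 and replicate 2, with exact 95% binomial intervals that cover counting error only. Cluster 8 holds 4.20% and 4.58%, whereas cluster 1 holds 30.1% of replicate 1 and 3.93% of replicate 2.

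A Tcf7 UMI was found in 6.02% ± 0.0835 of the T cells after thinning to 1500 UMIs (914 of 15042 and 877 of 14719 cells). It was found in 12% ± 1.86 before thinning, where all kept cells had median depths of 2688 and 3699 UMIs. Here and below, shares before thinning also cover the T cells under 1500 UMIs, so the set of cells differs too. In droplet data free RNA also gives such UMIs, so the share was also taken in clusters led by genes of other cell types, every cell again at 1500 UMIs. It was 0.613% (1 of 163 cells, exact interval 0.0155 to 3.37%) in the S100a8 cluster, 0.980% (1 of 102 cells, exact interval 0.0248 to 5.34%) in the epithelial cluster, 2.61% (3 of 115 cells, exact interval 0.541 to 7.43%) in the erythroid cluster and 6.06% (10 of 165 cells, exact interval 2.94 to 10.9%) in the myeloid cluster. In the myeloid cluster the share was 9.52% in replicate 1 and 2.47% in replicate 2. If all Ccl5 UMIs of the myeloid cluster were free RNA, with the profile of barcodes under 100 UMIs, that RNA would give Tcf7 UMIs in 1.58% of its cells. The share over all T cells lay above the intervals of the S100a8 and epithelial clusters and within those of the erythroid and myeloid clusters. None of the 4 is a clean background, since Cd3e, a T cell gene, had a UMI in 60.2% and 25% of the cells of the S100a8 cluster (replicates 1 and 2), 53.6% and 56.8% of the myeloid, 49.4% and 8.82% of the erythroid and 69.1% and 23.8% of the epithelial cluster. Among the T cell clusters the share differed by more than the spread between libraries. It was 0.705% ± 0.217 in cluster 2 and 0.916% ± 0.252 in cluster 9, against 7.43% ± 0.158 in cluster 6 and 16.6% ± 1.53 in cluster 11, which was led by Tcrg-C1, Dusp5, Tmem176b and Il7r. In cluster 8, which Tcf7 itself defines, it was 32.1% ± 0.945. Mki67, a gene of cycling cells, had a UMI in 5.32% ± 0.260 of the T cells at 1500 UMIs and in 11.9% before thinning. It was 9.20% (15 of 163 cells, exact interval 5.24 to 14.7%) in the S100a8 cluster, where free RNA estimated in the same way would give at most 2.25%. In the proliferating-like clusters 9 and 10, which such genes define, it was 20.9% ± 0.106 and 32.5% ± 4.14.

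**Figure D2:**
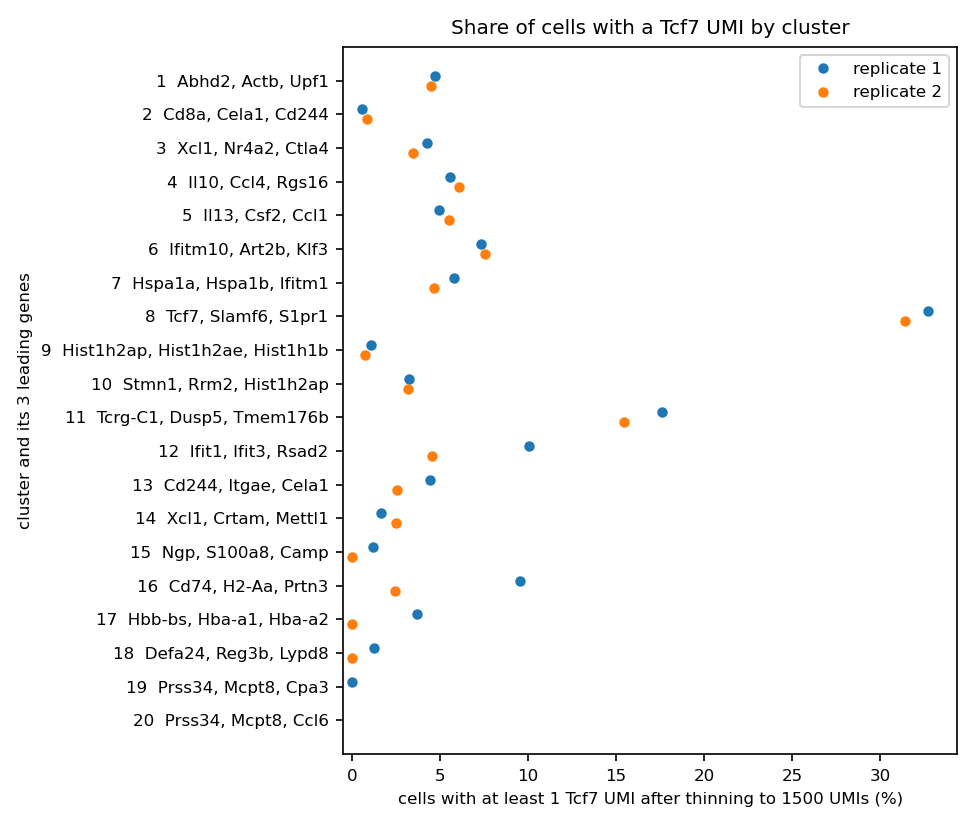
Share of cells with at least 1 Tcf7 UMI after thinning to 1500 UMIs (x axis, %) in each cluster (y axis, with the 3 leading genes), 1 point per library. Clusters 8 and 11 stand apart at 32.1% ± 0.945 and 16.6% ± 1.53, and no point is drawn for a cluster with under 20 cells in a library.

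Tcf7 (mm10, ENSMUSG00000000782, chromosome 11, 52252371 to 52283014) divided the cells into 914 Tcf7-detected and 14128 undetected cells in replicate 1, and 877 and 13842 in replicate 2. Slamf6, Klf2 and Il7r rose in the Tcf7-detected cells, and Gzma, Gzmb, Ccl5 and Itgae fell. Slamf6, a surface receptor used to mark progenitor T cells (ENSMUSG00000015314, chromosome 1, 171917515 to 171953170), had the largest rise among genes at 50 CPM or more, at 95.4 ± 1.10 against 27.0 ± 0.390 CPM (± SD, n = 2), a log2 fold change of 1.82 ± 0.12 (SE). Gzma (ENSMUSG00000023132, chromosome 13, 113093825 to 113100981) was at 4098 ± 636 against 16256 ± 499 CPM and fell by 1.99 ± 0.022 on the log2 scale. Of 11183 genes tested with edgeR's quasi-likelihood test, 496 rose and 537 fell at a Benjamini-Hochberg adjusted p under 0.05. The test used both libraries and so favours genes that move alike in them. Of these 1033 genes, 1032 moved the same way in both libraries, which is no independent replication.

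Of the progenitor or stem-like list, 9 of 13 measured genes rose and 0 fell (9 and 0 adjusted over the list alone, camera adjusted p = 1.23e-24, adjusted p = 0.332 with an estimated correlation). They included Id3 (log2 fold change 1.75 ± 0.21), Il7r, the receptor for the survival cytokine IL-7 (1.02 ± 0.065), and Bcl2, which protects from apoptosis (0.53 ± 0.062). Of the lymphoid retention and egress list, 8 of 10 measured genes rose and 0 fell (8 and 0 adjusted over the list alone, camera adjusted p = 1.67e-23, adjusted p = 0.332 with an estimated correlation). These were led by S1pr1, the receptor that draws lymphocytes out of tissue (1.54 ± 0.24), its regulator Klf2 (1.26 ± 0.054), Klf3 (1.25 ± 0.12) and the integrin gene Itgb1 (1.12 ± 0.10). Of the T follicular helper list, 3 of 7 measured genes rose and 0 fell (3 and 0 adjusted over the list alone, camera adjusted p = 6.89e-05, adjusted p = 0.341 with an estimated correlation). The rises were Cxcr5 (2.02 ± 0.41), Izumo1r (1.19 ± 0.13) and Sh2d1a (0.50 ± 0.057). Without the progenitor-like cluster Cxcr5 was at -0.15 ± 0.88 (edgeR adjusted p 0.968, with 7.34e-24 to 0.968 over the alternatives tried). Its rise was thus not seen outside that cluster, but the SE is too wide to exclude one. Of the ribosomal protein list, 10 of 13 measured genes rose and 0 fell (11 and 0 adjusted over the list alone, camera adjusted p = 9.35e-19, adjusted p = 0.332 with an estimated correlation), all by small amounts such as those of Rplp1 (0.37 ± 0.026) and Rps27a (0.33 ± 0.024). Of the immediate early and heat shock list, 7 of 16 measured genes rose and 0 fell (8 and 0 adjusted over the list alone, camera adjusted p = 2.62e-05, adjusted p = 0.424 with an estimated correlation), among them Junb (0.29 ± 0.026) and Ier2 (0.30 ± 0.046). Rflnb (1.31 ± 0.15), Dgka (1.17 ± 0.11), Ripor2 (1.17 ± 0.11), Ehd3 (1.14 ± 0.13) and Kbtbd11 (1.11 ± 0.13) were outside these lists and among the 10 largest rises.

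Of the cytotoxic list, 0 of 10 measured genes rose and 6 fell (0 and 7 adjusted over the list alone, camera adjusted p = 6.68e-92, adjusted p = 0.332 with an estimated correlation), including Gzmb (log2 fold change -1.66 ± 0.027) and Nkg7 (-0.54 ± 0.028). Of the type 1 helper list, 2 of 11 measured genes rose and 4 fell (2 and 4 adjusted over the list alone, camera adjusted p = 1.33e-17, adjusted p = 0.332 with an estimated correlation). Ccl3 (-0.87 ± 0.043), Ccl4 (-0.82 ± 0.026), Ccl5 (-0.70 ± 0.018) and Ifng (-0.57 ± 0.040) fell, while the chemokine receptor gene Cxcr3 rose (0.93 ± 0.086). The median of that list was 0.12 and its mean -0.098, and camera's direction was down, so the median differs in sign from the mean and the test. Of the checkpoint list, 0 of 11 measured genes rose and 4 fell (0 and 5 adjusted over the list alone, camera adjusted p = 2.65e-07, adjusted p = 0.332 with an estimated correlation). Those that fell were Havcr2 (-1.24 ± 0.16), Lag3 (-1.16 ± 0.086), Cd160 (-1.08 ± 0.070) and Entpd1 (-0.60 ± 0.14). Pdcd1, which encodes PD-1, was at 124 ± 11.9 against 132 ± 20.4 CPM and Tox at 109 ± 28.7 against 102 ± 21.8 CPM, with edgeR adjusted p-values of 0.652 and 0.656. Foxp3 and Il17a were too low to be tested. Of the proliferation list, 0 of 16 measured genes rose and 16 fell (0 and 16 adjusted over the list alone, camera adjusted p = 7.27e-20, adjusted p = 0.332 with an estimated correlation), such as Mki67 (-0.77 ± 0.17), Rrm2 (-0.92 ± 0.10) and Ube2c (-0.89 ± 0.12). Of the cholesterol synthesis list, 0 of 11 measured genes rose and 7 fell (0 and 9 adjusted over the list alone, camera adjusted p = 1.13e-05, adjusted p = 0.332 with an estimated correlation), such as Idi1 (-0.89 ± 0.15) and Fdps (-0.73 ± 0.12).

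Of the tissue residency list, 1 of 16 measured genes rose and 5 fell (1 and 6 adjusted over the list alone, camera adjusted p = 1.01e-07, adjusted p = 0.332 with an estimated correlation). Itgae, the integrin chain that binds epithelial E-cadherin, was at 92.0 ± 9.07 against 265 ± 15.1 CPM (log2 fold change -1.52 ± 0.084). Itga1 (-1.13 ± 0.14), Rgs1 (-0.57 ± 0.038) and Cxcr6 (-0.40 ± 0.046) also fell, as did the gut-homing chemokine receptor gene Ccr9 (-1.13 ± 0.11). Cd69 rose by 0.14 ± 0.036, with 0.23 in replicate 1 and 0.051 in replicate 2. Cd8a (-1.62 ± 0.064), Tcrg-C4 (-1.57 ± 0.10), Cd244 (-1.49 ± 0.15), Lat2 (-1.59 ± 0.17), Actn2 (-1.48 ± 0.089) and Spp1 (-1.93 ± 0.12) were among the 10 largest falls without clusters 15, 19 and 20. Markers of other cell types moved as well. Of the list for CD8, NK or gamma-delta cells, 2 of 9 measured genes rose and 4 fell (2 and 5 adjusted over the list alone, camera adjusted p = 2.60e-07, adjusted p = 0.332 with an estimated correlation). Of the myeloid list, 0 of 9 measured genes rose and 6 fell (0 and 7 adjusted over the list alone, camera adjusted p = 6.94e-44, adjusted p = 0.332 with an estimated correlation). Neutrophil and basophil genes had the 6 largest falls among genes at 50 CPM or more with all clusters in, namely Prss34 (-3.28 ± 0.26), Ngp (-2.71 ± 0.11), Camp (-2.65 ± 0.11), S100a8 (-2.59 ± 0.063), Lcn2 (-2.53 ± 0.19) and S100a9 (-2.49 ± 0.057). Without clusters 15, 19 and 20, which these genes lead, S100a8 was at -0.049 and 0 of these 6 genes passed, while 989 genes were called, of which 976 were among the 1033.

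The Tcf7 classes rest on whether 1 UMI was drawn, so the undetected class also holds cells that express the gene. The fit had 1 residual degree of freedom: camera called 19 of 28 lists with a preset correlation and 0 with an estimated one (lowest adjusted p 0.332), and the lowest adjusted p of fry was 0.0578. A second random thinning called 803 genes, of which 642 were among the 1033. The count was 282 at 1000 UMIs, 3117 without thinning, 614 without the progenitor-like cluster, 246 without the replicate block and 285 by DESeq2.

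**Figure D3:**
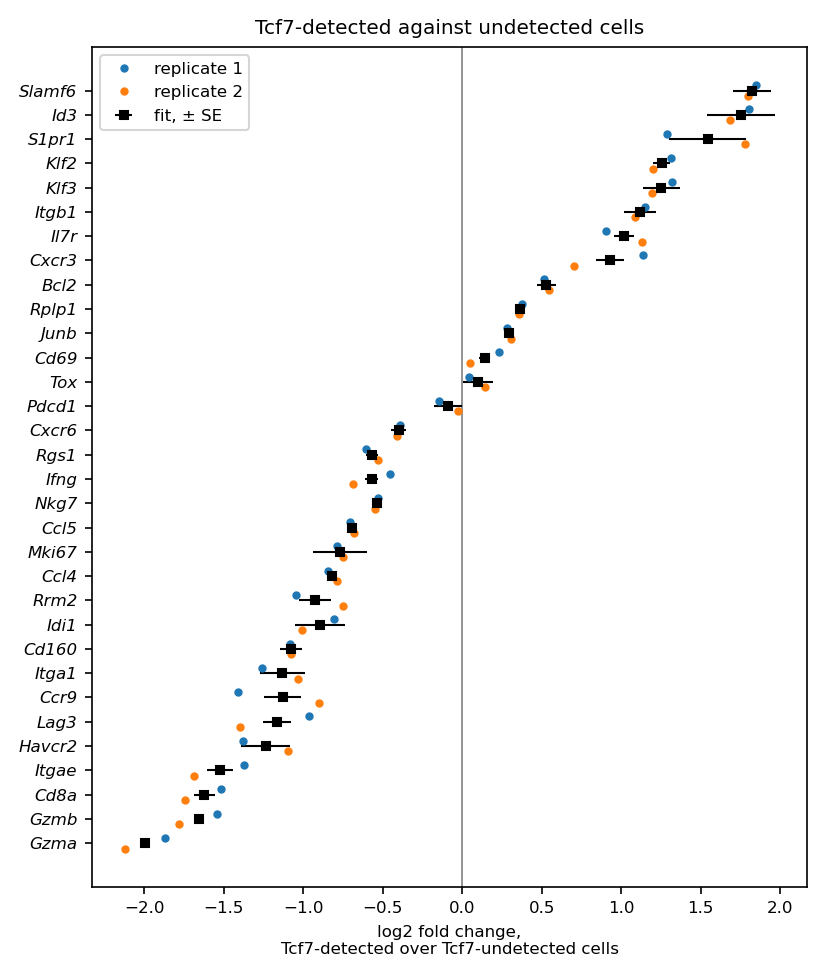
Log2 fold change (x axis) of Tcf7-detected over Tcf7-undetected cells for 32 named genes (y axis). Squares are the edgeR fit with its SE and dots the value in each library. Genes run from Slamf6 at 1.82 to Gzma at -1.99.

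Itgae (mm10, ENSMUSG00000005947, chromosome 11, 73090583 to 73147446) was detected in 25.5% ± 0.553 of the cells, and in 39.3% before thinning. Among clusters 15 to 18, the highest share was 12.9% (21 of 163 cells, exact interval 8.16 to 19.0%), in the S100a8 cluster. It was 21.7% there in replicate 1, against 25.1% in T cells, and 3.75% in replicate 2, against 25.9%. With Cd3e in 60.2% of that cluster's cells in replicate 1 and in 25% in replicate 2, this share is no clean background. Gzma, Gzmb, Cd8a and Ccr9 rose in the Itgae-detected cells, and Tcf7, Slamf6, Klf2 and Nfkbia fell. Itgae had a UMI in 64.5% ± 1.24 of the cells of cluster 2 and 3.17% ± 0.511 of cluster 8. Cluster 2 is led by Cd8a, Cela1, Cd244, Itgae and Gzma, and Tcf7 had a UMI in 0.705% ± 0.217 of it. The Itgae and Tcf7 splits are therefore not independent results, and no alternative left out cluster 2. Gzma was at 32272 ± 64.1 against 9726 ± 848 CPM (log2 fold change 1.73 ± 0.028, SE) and Gzmb at 9306 ± 313 against 3775 ± 321 CPM (1.30 ± 0.021). Cd8a was at 1008 ± 10.8 against 294 ± 40.3 CPM (1.78 ± 0.049), and Cd8b1 at 71.2 ± 9.20 against 39.1 ± 1.26 CPM (0.87 ± 0.082). Tcf7 was at 17.3 ± 2.11 against 56.0 ± 0.00424 CPM (-1.69 ± 0.095). Of 11161 genes tested by edgeR's quasi-likelihood test, 1277 rose and 1508 fell. As the test favours such genes, 2784 of these 2785 moving the same way in both libraries is no independent replication.

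Of the cholesterol synthesis list, 11 of 11 measured genes rose and 0 fell (11 and 0 adjusted over the list alone, camera adjusted p = 3.34e-12, adjusted p = 0.456 with an estimated correlation), such as Fdps (log2 fold change 0.81 ± 0.052) and Hmgcs1 (0.76 ± 0.065). Of the gut homing list, 3 of 4 measured genes rose and 1 fell (3 and 1 adjusted over the list alone, camera adjusted p = 6.12e-05, adjusted p = 0.456 with an estimated correlation). The rises were Ccr9 (1.19 ± 0.047), Ahr, a sensor of dietary and microbial ligands (0.77 ± 0.078), and Itgb7, which encodes the partner chain of Itgae (0.53 ± 0.046). Of the cytotoxic list, 4 of 10 measured genes rose and 2 fell (4 and 2 adjusted over the list alone, camera adjusted p = 1.11e-07, adjusted p = 0.456 with an estimated correlation). Itga1 (1.36 ± 0.054), Cd160 (1.21 ± 0.036) and Lag3 (0.81 ± 0.042) rose too, and the 10 largest rises held Gpr55 (1.91 ± 0.11), Lyl1 (1.80 ± 0.11), Cd244 (1.77 ± 0.058), Cela1 (1.73 ± 0.059) and Ncf1 (1.70 ± 0.076). Tox rose (0.31 ± 0.051), whereas Pdcd1 fell (-0.55 ± 0.054). Cd69 (-0.056 ± 0.028) and Cxcr6 (0.037 ± 0.033), both used as residency markers, did not pass, with edgeR adjusted p-values of 0.180 and 0.470. Markers of other cell types moved with Itgae. Of the epithelial list, 4 of 12 measured genes rose and 0 fell (4 and 0 adjusted over the list alone, camera adjusted p = 0.00436, adjusted p = 0.457 with an estimated correlation). Of the list for CD8, NK or gamma-delta cells, 3 of 8 measured genes rose and 4 fell (4 and 4 adjusted over the list alone, camera adjusted p = 0.0111, adjusted p = 0.457 with an estimated correlation), with a median of -0.096, a mean of 0.036 and an upward camera direction.

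Of the progenitor or stem-like list, 0 of 14 measured genes rose and 12 fell (0 and 12 adjusted over the list alone, camera adjusted p = 1.23e-18, adjusted p = 0.456 with an estimated correlation), such as Slamf6 (log2 fold change -1.67 ± 0.11) and Il7r (-0.81 ± 0.070). Of the lymphoid retention and egress list, 0 of 10 measured genes rose and 10 fell (0 and 10 adjusted over the list alone, camera adjusted p = 2.72e-22, adjusted p = 0.456 with an estimated correlation). These included S1pr1 (-2.09 ± 0.22), Klf2 (-1.40 ± 0.051), Klf3 (-1.70 ± 0.12) and Itgb1 (-1.63 ± 0.098). Of the NF-kB and TNF response list, 0 of 12 measured genes rose and 12 fell (0 and 12 adjusted over the list alone, camera adjusted p = 1.96e-13, adjusted p = 0.456 with an estimated correlation), among them Nfkbid (-0.85 ± 0.067) and Nfkbia (-0.73 ± 0.028). Of the immediate early and heat shock list, 0 of 16 measured genes rose and 15 fell (0 and 15 adjusted over the list alone, camera adjusted p = 2.19e-11, adjusted p = 0.456 with an estimated correlation), such as Zfp36 (-0.70 ± 0.048). Of the glycolysis and hypoxia list, 0 of 12 measured genes rose and 10 fell (0 and 11 adjusted over the list alone, camera adjusted p = 6.14e-08, adjusted p = 0.456 with an estimated correlation), such as Hif1a (-0.83 ± 0.043) and Tpi1 (-0.55 ± 0.053). Of the ribosomal protein list, 0 of 13 measured genes rose and 12 fell (0 and 13 adjusted over the list alone, camera adjusted p = 3.24e-06, adjusted p = 0.456 with an estimated correlation), by small amounts such as that of Rps2 (-0.39 ± 0.022). Single genes that fell were Eomes (-1.93 ± 0.086), Il10 (-1.89 ± 0.092), Il21 (-1.65 ± 0.21), Ccr2 (-1.59 ± 0.068), the co-stimulatory receptor gene Cd28 (-1.44 ± 0.057), Cxcr3 (-1.09 ± 0.062), Ifng (-0.76 ± 0.030) and Tnf (-0.69 ± 0.049). Mki67 fell by 0.26 ± 0.078 on the log2 scale, and its direction turned without thinning (0.093), where it did not pass. S100a8 fell too, with -1.04 in replicate 1 and -2.30 in replicate 2, and without clusters 15, 19 and 20 it was at -0.12 and 3040 genes were called, of which 2723 were among the 2785. The fit had 1 residual degree of freedom, and camera called 20 of 28 lists with the preset and 0 with the estimated correlation. The count of genes was 1972 at 1000 UMIs, 6211 without thinning, 1214 without the replicate block and 794 by DESeq2.

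Pdcd1 (mm10, ENSMUSG00000026285, chromosome 1, 94038305 to 94052553) was detected in 14.1% ± 1.5 of the cells, and in 26.0% before thinning. Among clusters 15 to 18, the highest share was 9.80% (10 of 102 cells, exact interval 4.80 to 17.3%), in the epithelial cluster. All of those cells came from replicate 1, where the share was 12.3% against 15.1% in T cells, and replicate 2 had 0% of 21 cells. With Cd3e in 69.1% of that cluster's cells in replicate 1 and in 23.8% in replicate 2, this share is no clean background either. Csf2, Ccl1 and Ifng rose in the Pdcd1-detected cells, and Gzma and Cd8a fell. Pdcd1 had a UMI in 38.9% ± 5.44 of the cells of cluster 5 and 4.31% ± 0.0832 of cluster 2. Csf2, Ccl1, Il13, Il1r2, Tnfsf11, Lmna and Atf3 are leading genes of cluster 5, and Gzma, Cd8a and Cd244 of cluster 2. Changes in these genes may reflect which clusters the cells came from, and no alternative left out either cluster. Csf2, which encodes the cytokine GM-CSF, was at 352 ± 22.4 against 115 ± 6.32 CPM (log2 fold change 1.61 ± 0.051, SE), and the chemokine gene Ccl1 at 1089.5 ± 38.4 against 318 ± 17.1 CPM (1.78 ± 0.038). Ifng was at 1416 ± 252 against 809 ± 65.0 CPM (0.80 ± 0.035). Gzma was at 7508 ± 226 against 16705 ± 748 CPM (-1.15 ± 0.030). Tcf7 was at 47.2 ± 0.495 against 46.0 ± 1.03 CPM, with an edgeR adjusted p of 0.867. By edgeR's quasi-likelihood test, 1052 of 11258 genes rose and 768 fell. Here too the test favours genes that move alike, and 1812 of these 1820 moved the same way in both libraries.

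Of the NF-kB and TNF response list, 12 of 12 measured genes rose and 0 fell (12 and 0 adjusted over the list alone, camera adjusted p = 1.09e-24, adjusted p = 0.402 with an estimated correlation), such as Nfkb1 (log2 fold change 0.79 ± 0.056), Traf1 (0.72 ± 0.044) and Rel (0.61 ± 0.064). Of the glycolysis and hypoxia list, 11 of 12 measured genes rose and 0 fell (11 and 0 adjusted over the list alone, camera adjusted p = 9.25e-17, adjusted p = 0.402 with an estimated correlation), such as Tpi1 (0.76 ± 0.058) and Hif1a (0.65 ± 0.044). Of the type 1 helper list, 8 of 11 measured genes rose and 2 fell (8 and 2 adjusted over the list alone, camera adjusted p = 7.35e-08, adjusted p = 0.402 with an estimated correlation), with Il18r1 (0.93 ± 0.059) and Tbx21 (0.66 ± 0.090) among the rises. Of the type 2 helper list, 4 of 6 measured genes rose and 0 fell (5 and 1 adjusted over the list alone, camera adjusted p = 4.32e-05, adjusted p = 0.402 with an estimated correlation), with Gata3 (0.61 ± 0.070) and Il13 among the rises. Il13 had 1.90 in replicate 1 and 0.97 in replicate 2, and Il22 had 2.53 in replicate 1 and 0.97 in replicate 2, so their fitted values of 1.46 ± 0.067 and 1.97 ± 0.16 have SEs smaller than the gap between libraries. Of the regulatory T cell list, 6 of 7 measured genes rose and 1 fell (6 and 1 adjusted over the list alone, camera adjusted p = 8.63e-14, adjusted p = 0.402 with an estimated correlation). The rises included Il2ra (1.35 ± 0.10) and Tnfrsf4 (1.08 ± 0.049), which activated T cells also express. Il1r2 (1.80 ± 0.078), Tnfsf11 (1.67 ± 0.067), Sdc4 (1.65 ± 0.090), Tnfsf9 (1.43 ± 0.088) and Lmna (1.38 ± 0.047) were among the 10 largest rises. Icos (1.22 ± 0.050), Ccr8 (1.82 ± 0.18), Il7r (0.78 ± 0.053) and Cxcr6 (0.76 ± 0.037) rose too, as did Ccr7, with 1.47 in replicate 1 and 0.81 in replicate 2. Of the checkpoint list, 3 of 10 measured genes rose and 3 fell (3 and 3 adjusted over the list alone, camera adjusted p = 0.831, adjusted p = 0.902 with an estimated correlation), with Havcr2 (0.99 ± 0.074) and Nr4a3 (0.99 ± 0.10) among the rises. The median of the checkpoint list was -0.14 and its mean 0.062, which differ in sign. Tox was at 94.6 ± 25.0 against 103 ± 21.2 CPM, with an edgeR adjusted p of 0.243. Of the immediate early and heat shock list, 11 of 16 measured genes rose and 1 fell (11 and 1 adjusted over the list alone, camera adjusted p = 1.07e-09, adjusted p = 0.402 with an estimated correlation), such as Atf3 (1.05 ± 0.059) and Hspa1a (0.49 ± 0.051).

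Of the interferon-stimulated list, 0 of 15 measured genes rose and 8 fell (1 and 8 adjusted over the list alone, camera adjusted p = 4.00e-08, adjusted p = 0.402 with an estimated correlation), such as Isg15 (log2 fold change -0.65 ± 0.053) and Ifi27l2a (-0.54 ± 0.039). Of the gut homing list, 0 of 5 measured genes rose and 3 fell (0 and 4 adjusted over the list alone, camera adjusted p = 3.25e-07, adjusted p = 0.402 with an estimated correlation), such as Ccr9 (-1.08 ± 0.078) and Itgae (-0.65 ± 0.054). Of the proliferation list, 0 of 16 measured genes rose and 11 fell (0 and 12 adjusted over the list alone, camera adjusted p = 1.05e-06, adjusted p = 0.402 with an estimated correlation). Mki67 was at 40.3 ± 8.03 against 42.5 ± 0.613 CPM (edgeR adjusted p 0.764), with a log2 fold change of -0.064 ± 0.10. It passed in opposite directions at 1000 UMIs (-0.39) and without thinning (0.17, edgeR adjusted p 0.00292), with 0.00292 to 1.000 over the alternatives tried. Cd8a (-1.14 ± 0.047), Cd244 (-1.16 ± 0.093) and Gzmb (-0.98 ± 0.031) fell. S1pr1 fell as well, with -1.43 in replicate 1 and -0.27 in replicate 2, and so did Klf2, with -0.46 in replicate 1 and -0.20 in replicate 2. Slamf6 (-0.16 ± 0.12) and Il17a (0.73 ± 0.53) did not pass. Cd69 rose by 0.10 ± 0.036 and did not pass in 8 of 13 alternatives. Markers of other cell types moved here too. Of the myeloid list, 0 of 10 measured genes rose and 5 fell (1 and 6 adjusted over the list alone, camera adjusted p = 1.60e-06, adjusted p = 0.402 with an estimated correlation). S100a8 was at -1.49 ± 0.044, and at 0.12 without clusters 15, 19 and 20, where 1608 genes were called, of which 1603 were among the 1820. The fit had 1 residual degree of freedom, and camera called 19 of 28 lists with the preset and 0 with the estimated correlation. The count of genes was 1171 at 1000 UMIs and 3306 without thinning. It was 601 without the replicate block (467 rose and 134 fell) and 449 by DESeq2 (346 rose and 103 fell). In both, the falls lost a larger share of their genes than the rises did.

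**Figure D4:**
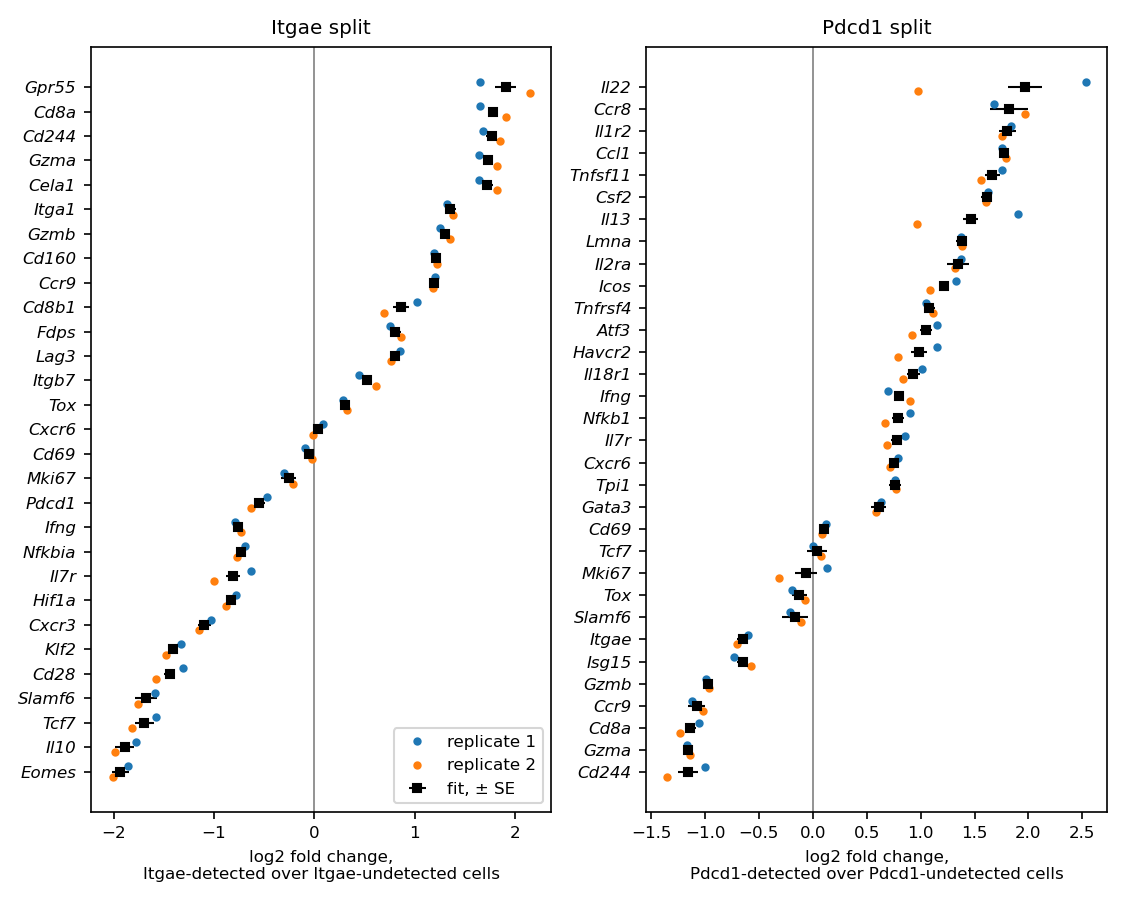
Log2 fold changes (x axes) of detected over undetected cells for named genes (y axes) in the Itgae split, left, and the Pdcd1 split, right. Squares are the edgeR fit with its SE and dots the value in each library, and Gzma lies at 1.73 in the Itgae split and at -1.15 in the Pdcd1 split.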

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

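Both tests of the hashtag libraries and the test of handling were chosen only after the result was seen. Gene UMIs were present in the hashtag libraries, which no comparison uses: 157432 in replicate 1 and 208698 in replicate 2, with a median of 3 and 4 per cell, led by Ccl5 and Gzma. Reads of unrelated libraries are argued against, because gene and barcode pairs recurred in the same cell of the expression library more often than in another cell of matched depth, by up to 27.2 percentage points. A candidate explanation is that cDNA of the same cells was read in both libraries, since the smaller of the 2 excesses was 24.4 percentage points (97.0% against 69.8% in replicate 1 and 95% against 70.6% in replicate 2). No biological explanation was tested, as the labels give no group that differs between the libraries.

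Cluster 1 came mostly from replicate 1. Lower depth per cell in that library is argued against as the whole cause: among cells with under 2000 UMIs, 69.8% of 6303 cells in replicate 1 and 21.2% of 1854 cells in replicate 2 were in the cluster, a ratio of 3.29. Barcodes that hold free RNA and no cell stay open, because 0 of 13 other T cell clusters had as high a correlation across genes with the free RNA profile (Spearman's rho 0.974 against 0.852 to 0.938), yet the other T cells summed together also reached 0.974, a comparison added after the result was seen. Handling of replicate 1 cannot be told apart from the animals, since 90.1% of the cluster came from 1 library and each replicate has 1 library. No biological explanation was tested.

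Neutrophil and basophil genes were lower in Tcf7-detected cells. Cells of another type among the Tcf7-undetected cells stay open by the test: 0 of the 6 genes Prss34, Ngp, Camp, S100a8, Lcn2 and S100a9 passed without the clusters led by S100a8 or Mcpt8, but all 6 are leading genes of those clusters, so this outcome was largely fixed by the choice of clusters. The cells of those clusters did lie almost wholly in the undetected class. Without them it went from 14128 to 13984 cells in replicate 1 and from 13842 to 13742 in replicate 2. The detected class went from 914 to 913 cells in replicate 1 and stayed at 877 in replicate 2. A sort for CD4 T cells would remove such cells, yet S100a8 reached 124912 ± 2894 CPM in cluster 15 (SD, n = 2). No biological explanation was tested.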

How the results depend on the processing

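Leaving out a library left no residual degree of freedom, so only values per library exist. They had the sign of the fit for 209 of 210 values in the Tcf7 split, 249 of 250 in the Itgae split and 233 of 236 in the Pdcd1 split. Most named genes were chosen by a fit on both libraries, and the largest changes by their same order in both. This agreement was therefore largely fixed by the choice of genes. Over the other alternatives, 1186 of 1364 values of named genes kept direction and side of the threshold in the Tcf7 split (168 no longer passed, 1 newly passed and 10 reversed, single libraries included), 1507 of 1619 in the Itgae split (100, 2 and 10) and 1379 of 1533 in the Pdcd1 split (132, 7 and 16). The Tcf7 split's 1033 genes became 282 at 1000 UMIs, 3117 without thinning, 614 without the progenitor-like cluster (525 shared), 246 without the replicate block and 285 by DESeq2. The Itgae split's 2785 became 6211 without thinning, 1214 without the block and 794 by DESeq2. The Pdcd1 split's 1820 became 1171 at 1000 UMIs, 3306 without thinning, 601 without the block and 449 by DESeq2. A second random thinning called 803, 3234 and 1854 genes, of which 642, 2323 and 1331 were among those of the first. With an estimated correlation, 0 lists passed in any split, against 19, 20 and 19 with the preset one. On 1 residual degree of freedom hardly any list could pass, so the 0 decides nothing about the lists. Of the genes printed in the report, the reversed values were Cxcr5 in the Tcf7 split without the progenitor-like cluster (-0.15), Mki67 without thinning in the Itgae (0.093) and Pdcd1 (0.17) splits, and, without clusters of S100a8 or Mcpt8 cells, Prss34 (0.52) and S100a9 (0.0044) in the Tcf7 split and S100a8 in the Pdcd1 split (0.12). The Tcf7 share of 6.02% became 4.13% at 1000 UMIs, 12% without thinning, 6.20% without clusters mostly of 1 library and 6.16% in a second thinning (5.96 to 6.08% by library). The Mki67 share of 5.32% became 3.75%, 11.9% and 4.93% under the former 3 (5.14 to 5.5%). Progenitor-like cells, 4.39%, were 4.94% of cells with 1500 UMIs, 13.2% at resolution 0.6 and 6.30% at 1.5 (4.20 to 4.58%). Proliferating-like cells, 8.02%, were 9.13% of cells with 1500 UMIs and 12% at resolution 1.5 (7.68 to 8.37% by library at resolution 1). At 1.5 they were 15.6% in replicate 1 and 8.39% in replicate 2, with 1833 cells of replicate 1 and 320 of replicate 2 in a cluster led by Abhd2. Interferon-response-like cells ranged from 0.98 to 1.97% by library at resolution 1 and from 1.20 to 2.53% at 1.5. At 0.6 a cluster of 264 cells led by Ifit3 and Ifit1 missed the 3 markers that the name needs, as did a cluster of 288 cells led by Ifit3 and Ifit1 at 1.5, which that range leaves out. Depth by construction changes the share of cells with a UMI, and the set of cells also changed at 1000 UMIs and without thinning. The cause of the other changes was not tested. Alternatives by tissue, hashtag rule, UMI minimum and mitochondrial limit were not run, nor was Scrublet's own doublet call.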

Other observations

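The clusters differed in cytokine transcripts. Cluster 5 had Csf2 at 919 ± 43.9 CPM, Il13 at 474 ± 141, Il2 at 237 ± 12.3 and Il22 at 51.2 ± 10.2 CPM (SD, n = 2 libraries), with Ifng at 1895 ± 112 CPM. Cluster 4 had Il10 at 271 ± 2.54 CPM, Eomes at 142 ± 1.30 and Ifng at 1393 ± 32.6 CPM. Cluster 14 had Xcl1 at 1725 ± 341 CPM. Gzma was at 48037 ± 4469 CPM in cluster 2, against 2083 ± 278 in cluster 5 and 1157 ± 63.1 in cluster 8. These genes were chosen after their values were seen, and several of them define their cluster.

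The proliferating-like clusters 9 and 10 differed in Gzma, Cd8a and Itgae. Cluster 9 had Gzma at 37204 ± 109 CPM, Cd8a at 979 ± 11.8 and Itgae at 379 ± 23.5 CPM, and cluster 10 had 1415 ± 11.1, 43.2 ± 7.48 and 32.0 ± 0.136 CPM. Eomes was at 9.54 ± 0.998 CPM in cluster 9 and 93.7 ± 2.17 in cluster 10, and Tcf7 at 5.43 ± 0.203 and 29.7 ± 4.61 CPM. Cd8a and Cd8b1 did not keep 1 ratio: cluster 2 had 1635 ± 119.7 and 105 ± 16.3 CPM, and cluster 8 had 41.9 ± 3.31 and 27.2 ± 4.94 CPM. Differences between clusters were not tested.

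The setting of the test that follows was added after seeing the data, and what it should show was written before it was run. Tcf7 detection may mark progenitor genes beyond the progenitor-like cluster. In the Tcf7 split without that cluster, 6 of 13 measured progenitor or stem-like genes rose and 0 fell, with a median log2 fold change of 0.68 (camera adjusted p = 1.28e-12 with the preset correlation, adjusted p = 0.358 with an estimated correlation). A doublet or a cell near the cluster's border was not separated from this. By the same naming rule, 13.2% of cells were progenitor-like at resolution 0.6, so some such cells may have stayed in. Tcf7 had a UMI in 16.6% ± 1.53 of cluster 11 and 0.705% ± 0.217 of cluster 2, and both clusters stayed in. The rises may therefore reflect differences among the remaining clusters, which was not tested.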
